A study of Homo sapiens with 2 samples.

How the data were processed

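CTCF ChIP-nexus was performed on crosslinked, sonicated chromatin of HEK293T cells with a CTCF antibody, per the labels' protocols. The labels give 2 libraries, replicate 1 and replicate 2, which form 1 group. Reads were processed with cutadapt and Bowtie2 against hg19, per the submitters' processing notes, which give no versions. The 2 deposited lists hold regions for the whole series, and whether the libraries were pooled before calling is not given in the sources used here. No library could be left out or compared with the other, and the depth of each library is unknown.

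The deposited MACS list gives chromosome, start, end, name and a score per peak. The authors' deposited score has a lowest value of 50, which equals a p of 1e-05 on a -10 log10 scale, but the scale itself is not given. The score was used only within the list, for ranks, differences and correlations. The differences and the Pearson correlations depend on the unknown scale. Peaks did not overlap each other. The deposited MACE list gives chromosome, both borders, a class code and a p-value per border pair. The authors' deposited p-value ran from 0.000293 to 0.0500, with a median of 0.00530. The codes were GSB in 33014 pairs, SFB in 2137 and SRB in 2060, and they were used only as names. Neither list has a header. Starts were read as counted from 0, as in BED files, and are printed counted from 1; with another convention positions and widths would move by 1 bp.

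A peak had a border pair if they shared at least 1 bp. Random expectation came from 100 seeded placements of the pairs on their own chromosome between the first and last region there, since chromosome lengths were not used. Differences of medians were tested by two-sided permutation with 100000 resamples, with 95% intervals from 1000 bootstrap draws. Shares have 95% Wilson intervals and densities exact Poisson intervals, both of which cover counting error of regions only. Shares per chromosome were compared by Fisher's exact test with Benjamini-Hochberg adjustment at a threshold of 0.05. Neighbouring regions are not independent, so p-values over regions can be too small. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The count of peaks with a pair was checked with bedtools 2.31.1, which also gave 25529.

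The overlap, score, correlation and per-chromosome steps were tested on simulated data with 52711 peaks. Random placements, distances of centres and the shuffle of pairs were not tested in this way. Simulated shares of 40% and, on chromosome 7, 60% were found as 40.1% and 60.4%, and a simulated score difference of 50 as 49.0 (46.9 to 51.1). Without a simulated effect the permutation p was 0.373. Of the chromosomes, 2 were called, chromosome 7 among them. Chromosome 7 alone was given another share, so the other call did not reflect a simulated difference.

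Before the data were examined, the comparisons, their alternatives and the rule for named sites were fixed, apart from additions given at the end of this paragraph. The rule takes the 10 peaks with the highest score on assembled chromosomes, the 5 highest without a border pair and the 5 with most border pairs, with ties ordered by chromosome and start. Comparisons fixed at the same time that need hg19 sequence or annotation were not made: CTCF motif content and orientation, border positions around the motif, promoter shares, gene lists and the protocadherin clusters. The gene table used here is for GRCh38 and gives no positions on hg19. The alternatives were a stricter overlap, a distance between centres, the stronger 50% of peaks, the 50% of pairs with the smaller p-values, autosomes only, narrow peaks and peaks with exactly 1 pair. Alternatives added after seeing the data were other random placements, GSB pairs only, assembled chromosomes only, leaving out windows dense in peaks or the largest peak-free span, and merged stretches. Peak width with and without a pair and the correlations among peaks with a pair were also not fixed beforehand. The same holds for the arrangement and extent of several pairs in 1 peak.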

Results

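CTCF binding was mapped by ChIP-nexus in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. CTCF is the zinc finger protein that binds insulators and the ends of many chromatin loops. In ChIP-nexus an exonuclease trims the immunoprecipitated DNA up to the crosslinked protein, so that the ends of the remaining DNA mark the borders of the protected stretch. The labels describe 2 libraries of 1 group, replicate 1 and replicate 2, with no control library. The values came as 2 region lists for the whole series, neither of which names a library: 52768 MACS peaks and 37211 MACE border pairs. No spread between replicates could therefore be given, and the read depth of both libraries is unknown. Intervals and p-values below describe the regions within these lists and not the variation between libraries.

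Of the 52768 peaks, 52302 lay on the 24 assembled chromosomes and 466 on 48 other contigs. Peaks had a median width of 143 bp (interquartile range 95 to 185 bp) and covered 7625747 bases in total. The score of a peak is the authors' own value and was used only within the list, for ranks, differences and correlations. Its scale is not given in the sources used here, and differences and Pearson correlations depend on it. It ran from 50 to 3230.05 with a median of 365. All positions are hg19 coordinates, with starts counted from 1. No hg19 sequence or gene annotation was used here, so sites are named by position and not by gene or motif.

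The first question was how far both callers named the same CTCF sites. A border pair overlapped 25529 of the 52768 peaks, or 48.4% (95% Wilson interval 48.0 to 48.8%). In the other direction, 36444 of the 37211 border pairs lay in a peak, or 97.9% (97.8 to 98.1%). Pairs placed at random on the same chromosome reached at most 0.370% of peaks and 0.556% of pairs in 100 placements (one-sided permutation p = 0.0099 for both, the smallest that 100 placements can give). Both lists were made from the same series and are not independent, so this p does not measure how well the callers match.

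The 767 border pairs outside peaks were concentrated on a few contigs. The unplaced contig chrUn_gl000220 held 173 of them, out of 176 pairs on that contig, which had 6 peaks. A further 90 lay on chr9_gl000199_random, 84 on chromosome X and 57 on the mitochondrial contig. Contigs other than the 24 assembled chromosomes held 368 of the 767 pairs outside peaks, or 48.0%, against 1.63% of all pairs.

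Strong peaks carried border pairs and weak peaks rarely did. The share of peaks with a pair was 2.05% (95% Wilson interval 1.70 to 2.46%) in the weakest decile by score, 27.8% (26.6 to 29.0%) in the fifth, 58.7% (57.4 to 60.04%) in the sixth and 98.4% (98.1 to 98.7%) in the strongest. The median score was 821 in the 25529 peaks with a pair and 128 in the 27239 peaks without one, a difference of 694 (95% bootstrap interval 687 to 700.3). A two-sided permutation test of the medians with 100000 resamples gave p = 1e-05, the smallest it can give. Scores and border pairs come from the same series and are not independent, so this p does not measure independent support. Peaks with a pair were also wider, with a median of 183 bp against 98 bp (difference 85 bp, 84 to 86 bp, permutation p = 1e-05). This width comparison was not fixed beforehand, and its p has the same limit.

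**Figure D1:**
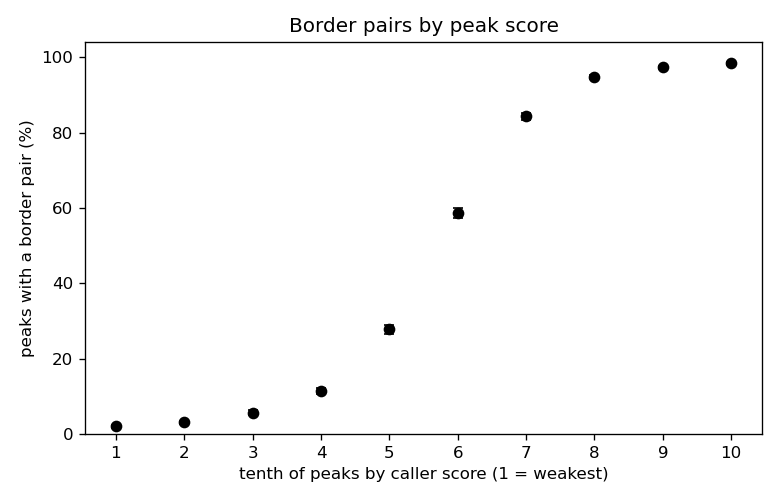
Share of peaks with a border pair (vertical axis, %) in each decile of the peaks ranked by caller score (horizontal axis, 1 = weakest); points are shares and bars 95% Wilson intervals. The share rose from 2.05% in the weakest decile to 98.4% in the strongest.

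Sites were named by a fixed rule. The highest score, 3230.05, belonged to a 411 bp peak at chromosome 12:94101-94511, which held 1 border pair of 47 bp. The next was at chromosome 19:34268945-34269242 (score 3160.6), with 1 pair of 38 bp. The third, at chromosome 9:134615410-134615731 (score 3159.65), held no border pair. The remaining 7 of the 10 highest all had a score of exactly 3100. Whether this value is a limit of the scale is not given in the sources used here, so the order of these 10 peaks may not be that of their signal. They lay at chromosome 1:121484053-121485441, 5:10002-11783, 6:58776208-58779878, 9:998518-999064, 16:60796-61174, 21:9825440-9827581 and X:10087507-10087950. Of these, the peaks on chromosomes 5 and 16 were the outermost peaks of their chromosome. The peak on chromosome 1 bordered the largest peak-free span of that chromosome, which was 21.1 Mb long. The peak on chromosome 6 lay 0.000288 Mb from that of its own. The peaks on chromosomes 1, 5, 6 and 21 were 1389, 1782, 3671 and 2142 bp wide, against a median of 143 bp over all peaks. Without a control library, signal not due to CTCF could not be told apart at these sites.

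Among peaks without a border pair, the 5 highest scores were 3159.65 at chromosome 9:134615410-134615731, 2920.71 at 15:102519663-102520024, 2597.88 at 9:141121264-141121562, 2592.32 at 11:180216-180506 and 2502.52 at X:152665592-152665844. The peaks at 15:102519663-102520024 and 9:141121264-141121562 were the outermost of their chromosome, and the peak at 11:180216-180506 lay 0.112 Mb from the outermost.

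The distance between paired borders is meant to give the length of DNA protected from the exonuclease, which was not tested here. Pairs can lie within another pair of the same peak, so a width need not be the whole protected length. The distance had a median of 38 bp over all pairs (interquartile range 22 to 48 bp), and the most frequent width was 46 bp, with 1060 pairs. Widths of 40 to 52 bp made up 32.4% of pairs, and 21.2% were narrower than 20 bp. Pairs inside peaks were narrower than pairs outside, with medians of 38 bp (n = 36444) and 47 bp (n = 767). The difference, inside minus outside, was -9 bp (95% bootstrap interval -10 to -8 bp; two-sided permutation p = 1e-05, the smallest the test can give). Each pair carries a class code, GSB, SFB or SRB, whose meaning is not given in the sources used here. GSB made up 89.7% of pairs inside peaks and 40.03% of those outside. Within GSB alone the difference was also -9 bp (-11 to -6 bp, permutation p = 1e-05). The medians inside and outside were 43 and 48 bp for SFB and 42 and 46 bp for SRB, for which the difference was not tested.

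**Figure D2:**
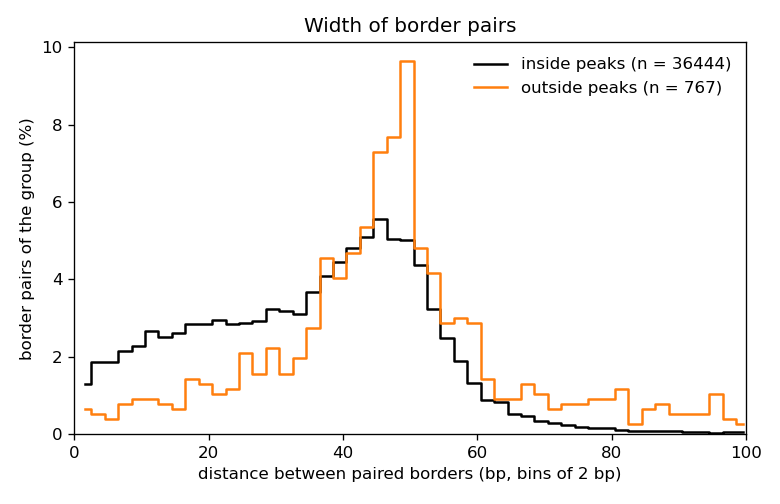
Percent of border pairs (vertical axis) by distance between the paired borders (horizontal axis, bp, in bins of 2 bp, up to 100 bp), for pairs inside peaks (black, n = 36444) and outside peaks (orange, n = 767). Pairs inside peaks extend further toward narrow widths, with 21.5% under 20 bp against 7.43% outside.

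Border pairs were centred on the peaks. In the 25529 peaks with a pair, the centre of the nearest pair lay a median of 9.5 bp from the peak midpoint (interquartile range 4 to 18 bp), and 79.7% lay within 20 bp. The median signed distance was 0 bp. A random position in the same peak gave a median of 43.7 bp on average and 43.1 bp at the least in 100 draws (one-sided permutation p = 0.0099, the smallest possible). The peak list gives no summit, so the midpoint was used.

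Most peaks with border pairs held 1 pair. There were 16293 peaks with 1 pair (30.9%; 95% Wilson interval 30.5 to 31.3%), 7661 with 2 (14.5%; 14.2 to 14.8%) and 1575 with 3 or more (2.98%; 2.84 to 3.13%). Median scores were 736, 919 and 949 in these groups. Across all 52768 peaks the number of pairs followed the score, with a Spearman rho of 0.773 and a Pearson r of 0.698. Among the 25529 peaks with a pair, rho was 0.246 and r was 0.207. Each of these 4 correlations had a permutation p and a Benjamini-Hochberg adjusted p of 1e-05, the smallest possible. They run across peaks, which are not independent replicates, and both lists come from the same series. In peaks of at most the median width, rho over all peaks was 0.459.

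Several pairs in 1 peak mostly overlapped or touched. Of the 9236 peaks with 2 or more pairs, 93.0% had pairs that joined in this way to form 1 stretch. In the 7661 peaks with exactly 2 pairs, 1 pair lay within the other in 47.0%, the pairs were staggered in 45.7% and they were separate in 7.32%. When the second pair was exchanged between peaks at its distance from the midpoint, the mean shares over 100 shuffles were 28.9%, 47.2% and 23.9% (two-sided permutation p = 0.0198 for each, the smallest possible). This shuffle was not fixed beforehand. It also breaks any offset from the midpoint that both pairs of a peak share, which can itself raise the separate share. These p-values therefore do not show how pairs are arranged around a shared centre. The stretch from the first to the last border had a median of 37 bp (95% bootstrap interval 37 to 38 bp) with 1 pair, 53 bp (52 to 53 bp) with 2 and 65 bp (63 to 66 bp) with 3.

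By the fixed rule, the peaks with most pairs were at chromosome 6:58776208-58779878 and 16:46402655-46407356 with 13 pairs each, 21:9825440-9827581 with 9, 16:46423545-46426057 with 6 and 2:13147137-13147305 with 5. The first 4 were between 2142 and 4702 bp wide. Both peaks on chromosome 16 had low scores, 83.31 and 176.46. The peak on chromosome 2 had a score of 737.14 and held its 5 pairs, 7 to 66 bp wide, within 169 bp.

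**Figure D3:**
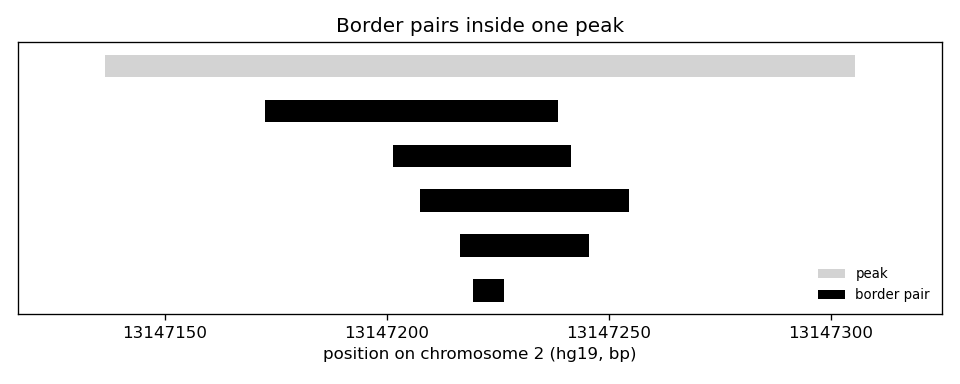
Map to scale of the peak at chromosome 2:13147137-13147305 (hg19, horizontal axis in bp; grey bar) and its 5 border pairs (black bars, 1 per line, vertical order without meaning). The pairs overlap, and their widths run from 7 to 66 bp.

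Peak density differed between chromosomes. Chromosome 19 had 34.5 peaks per Mb between the first and last region on it (exact Poisson 95% interval 33.0 to 36.0), chromosome 22 had 32.1 (30.2 to 34.0) and chromosome 17 had 30.3 (29.1 to 31.5). The lowest densities were on chromosome Y with 5.89 (5.28 to 6.54), chromosome 18 with 11.7 (10.9 to 12.4) and chromosome 13 with 12.5 (11.8 to 13.2). On chromosome Y, 217 of the 348 peaks lay in 6 windows of 100 kb with 20 or more peaks each, and the largest peak-free span took 30.0 of its 59.1 Mb. Its density was 2.24 without those windows and 11.9 without the peak-free span, both settings chosen after seeing the data. Whether HEK293T cells carry a chromosome Y was not checked here. The values for chromosome Y therefore describe only where reads were mapped. The share of peaks with a border pair was tested for each of 24 chromosomes against all other peaks (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 24). By this exact test it was higher on chromosomes 1 (50.6% against 48.1%, adjusted p = 0.00577) and 17 (51.8% against 48.2%, adjusted p = 0.00414). By the same exact test it was lower on chromosomes 4 (44.7% against 48.6%, adjusted p = 0.00276), 13 (43.8% against 48.5%, adjusted p = 0.00687) and Y (24.1% against 48.5%, adjusted p = 3.88e-19, 348 peaks). The median score was 410 on chromosome 1 and 447 on 17, and 305 on chromosome 4, 307 on 13 and 118 on Y, against 365 over all peaks, and the shares were not adjusted for score. Among the stronger 50% of peaks, 2 chromosomes passed the threshold in place of 5: chromosomes 1 and 4 did, and the calls for chromosomes 13, 17 and Y were lost.

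**Figure D4:**
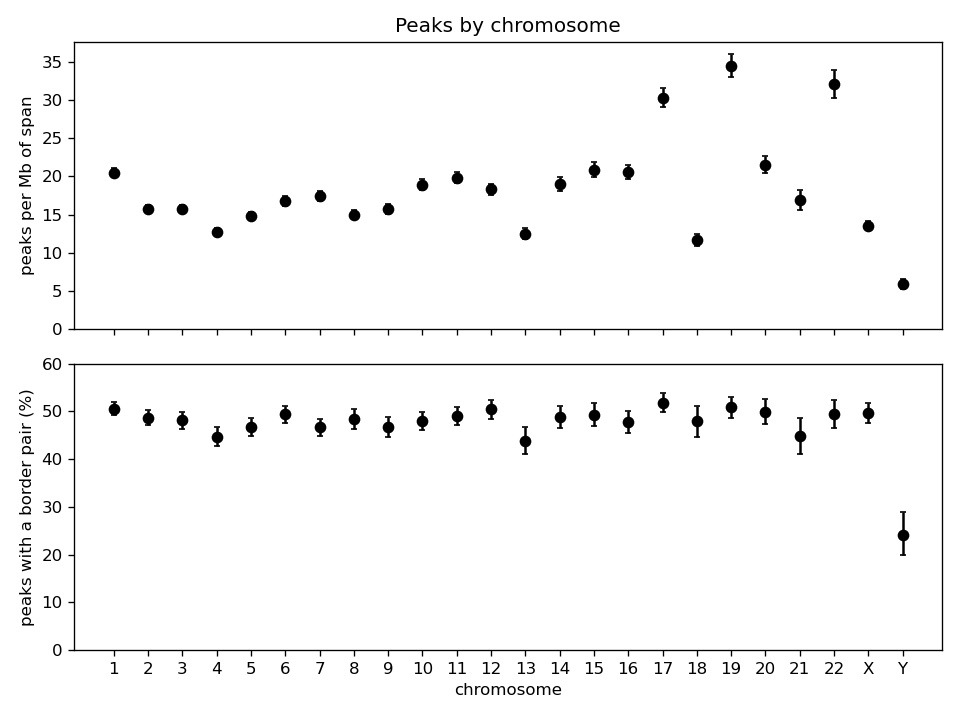
Peaks per Mb of the span between the first and last region of each chromosome (upper panel, exact Poisson 95% intervals) and percent of peaks with a border pair (lower panel, 95% Wilson intervals), by chromosome. Chromosomes 17, 19 and 22 have the most peaks per Mb, and chromosome Y has the lowest value in both panels, 5.89 peaks per Mb and 24.1%.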

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

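The mitochondrial contig was seen to hold border pairs only after the lists were read, and no test was planned for it. It is listed here because it carried 57 border pairs and 0 peaks; the pairs count among the 767 outside peaks. Of these pairs 19 had the class code GSB, 22 SFB and 16 SRB, and their median width was 48 bp. Their deposited MACE p-values had a median of 0.0268, against 0.00530 over all pairs. Over all pairs, the medians by class were 0.00468 for GSB, 0.0284 for SFB and 0.0287 for SRB. They lay between bases 223 and 16143 of the contig.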

How the results depend on the processing

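Alternatives with other placements, GSB pairs only, assembled chromosomes only, no dense windows, merged stretches or no peak-free span were chosen after seeing the data; the others were planned. Of 37 alternative values, 33 kept their direction and their side of the threshold, or stayed within the interval of a value with no test, and none reversed. Many of these compare overlap shares with random placement, which 2 lists from the same series could hardly fail to exceed. The count of 33 therefore says little about how stable the shares themselves are. The share of peaks with a pair ran from 29.9% with the 50% of pairs of smaller p-value to 86.7% among the stronger 50% of peaks. The share of pairs inside a peak ran from 90.3% among the stronger 50% of peaks to 99.3% with the smaller p-values. Shifting pairs by 5 to 50 kb gave at most 0.606% of peaks and 0.911% of pairs. The score difference was 694 at 50% overlap and 696 on assembled chromosomes. The median pair width moved from 38 bp to 37 bp with the smaller p-values, with GSB pairs only and without dense windows. The width difference ran from -10 to -8.5 bp. The distance of pair centre to midpoint was 12 bp in peaks with exactly 1 pair. The correlation of pairs with score was 0.459 in peaks of at most the median width and 0.777 on assembled chromosomes. Chromosomes called fell from 5 to 2 among the stronger 50% of peaks, chromosomes 1 (Fisher's exact test, adjusted p = 0.0258) and 4 (adjusted p = 0.0157); the cause was not tested. All 17 named peaks had the same number of pairs at 50% overlap. With the smaller p-values, all 12 named peaks that held pairs lost some: 10 fell to 0 pairs and 2 to 1. The cut lay at the median of the deposited MACE p-values, 0.00530. Their median was 0.00663 in the strongest decile of peaks against 0.00160 in the fifth, so this cut tends to remove pairs from the strongest peaks. Not run were the alternatives of the motif, promoter, gene list and protocadherin comparisons, which need hg19 sequence or annotation. A second peak measure, a caller summit and leaving out a replicate were not run either, since the lists used here hold none of these values. No paired analysis was possible because neither list has values per library. Read depth is unknown here, so how far it limits border pairs in weak peaks was not assessed.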

Other observations

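Apart from 3 tests whose bounds were set before their own values were seen (the dense windows matched on score and width, and both tests of pair p-values among pairs alone in their peak), the tests in this part were chosen after the results were seen. Some were also changed after a first value. The width of strong peaks without a pair was first compared without matching on score, and the dense windows were first counted by peak and then by window; both versions are given.

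CTCF peaks with a border pair lay closer together than random placement gave. Among 22807 distances between neighbouring peaks of this kind in the stronger 50%, 1.35% were under 1 kb, against at most 1.20% in 100 placements along the chromosome. Placement within the same 1 Mb gave up to 1.61% at that distance, so regional density was enough there. Under 10 kb, the share was 12.4%, above the highest of 11.8% from placement within the same 1 Mb (one-sided permutation p = 0.0099, the smallest possible).

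Strong peaks without a border pair lay near the outermost peak of their chromosome, here called an end, more often than those with one, although 58 of 77 lay elsewhere. The outermost peak need not lie at the chromosome end. On chromosome 21, the peak at 21:9825440-9827581 lay 0.340 Mb from the outermost peak. In the strongest decile by score on assembled chromosomes, 19 of 77 peaks without a pair lay within 1 Mb of the outermost peak (24.7%, 95% Wilson interval 16.4 to 35.4%), against 141 of 5182 with a pair (2.72%; odds ratio 11.7, Fisher's exact p = 5.8e-13); the 50 peaks with a pair nearest in score gave 3.14 expected in place of 19 (one-sided p = 1e-05 from 100000 draws, the smallest possible), although 5 of the 9 peaks with a pair among the 10 highest scores also lay this near an end. Lower peak scores are argued against for the 77 peaks as a set, since the median score without a pair was higher by 76.8 (95% interval 14.7 to 213.9). The score is given per peak and was not compared for the 19 near an end alone, so weaker signal at their borders stays open. Borders blurred over wider peaks may contribute: peaks without a pair were wider by 21 bp (1 to 46 bp), but only by 2 bp (-5 to 17.5 bp) than the 50 peaks with a pair nearest in score, and against these matched peaks the excess was 44 bp (2 to 98 bp) in the 19 near an end and -2.5 bp (-10.5 to 5.75 bp) in the 58 elsewhere, so width stays open. Sequence shared between chromosome ends also stays open without hg19 sequence, and no biological explanation was tested.

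Most windows dense in peaks held weak peaks. On assembled chromosomes, 44 windows of 100 kb held 20 or more peaks, 1282 in all (2.43% of peaks), with a median score of 100.1 against 385 elsewhere; in 3 windows the median was above that of all peaks. The densest were Y:13800001-13900000 with 63 peaks and 4:49100001-49200000 with 43. Sites like those of the same score elsewhere are argued against only as far as score and width describe a site. Over 51 such windows on all contigs, 588 peaks had a pair. That was 3.16 times (2.42 to 4.15) the number expected from score, and 1.87 times (1.64 to 2.13) that from score and width. Reads were not used and the scale of the score is not given, so equal scores need not mean equal signal. A candidate explanation is arrays of repeats beside the large peak-free spans: 74.5% of these peaks lay within 2 Mb of the largest such span of their chromosome, against 3.54% of other peaks, and 77.3% of the windows did, against 3.00% (Fisher's exact p = 7.91e-43). The other 10 windows, among them the densest at 14.9 Mb, did not lie this near to that span. Only the largest span of each chromosome was measured, so these windows do not decide about arrays beside other spans. Repeat content was not analysed here and no biological explanation was tested.

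Border pairs had larger p-values in stronger peaks. Across 32714 overlaps of GSB pairs with peaks, pair p and peak score had a Spearman rho of 0.420 and a Pearson r of 0.370 (permutation p and adjusted p = 1e-05, the smallest possible, 8 correlations in the family; regions are not independent replicates). The median pair p fell from 0.00560 in the weakest decile of peaks to 0.00160 in the fifth and rose to 0.00663 in the strongest. Extra pairs in strong peaks are argued against, with rho = 0.449 among pairs alone in their peak, as is pair width, with rho of at least 0.4001 in each of 5 width classes. The way the border caller forms its p-value may account for the pattern and stays open, since the smallest p of each peak gave rho = 0.444 and the reads behind each border were not used here; no biological explanation was tested.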
